A study of Mus musculus with 21 samples.

How the data were processed

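Total RNA from 21 cultures of mouse calvarial osteoblasts, 3 for each of 7 treatments, was labelled from 100 ng and hybridised to Affymetrix Mouse Gene 2.0 ST arrays. The deposited table gave signals, read here as log2, for which the submitters' processing notes name RMA and Affymetrix Expression Console. RMA by its usual steps comprises background correction, quantile normalization and probe set summary, but the notes state no steps, versions, settings or base of the logarithm. The values were read as log2 from the method and their range, so every log2 difference and fold rests on that reading. They ran from 0.25 to 13.6 with near-equal quartiles in all 21 columns (lower quartiles 2.19 to 2.30, upper quartiles 5.74 to 5.82). No array was left out and no column was unused. Arrays give no read depth, and their number limits the precision.

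The table held 41345 transcript clusters. The platform annotation named 25335 of them, 23521 with 1 gene symbol and 1814 with several, and 16010 were not in it, which leaves them unnamed here rather than without a gene. Symbols were compared with the RefSeq table through 23328 gene identifiers and 0 differed. Clusters with 1 symbol were used, and where a gene had several clusters (1082 genes) the one with the highest mean over all arrays stood for it, which left 22180 genes. Clusters without a single symbol were left out of the comparisons because no gene can be named for them. Their counts stand in the closing section.

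All 21 arrays entered 1 linear model of 7 groups in limma 3.58.1 (R 4.3.3, lmFit and eBayes), so that each gene had 1 estimate of its spread. Each analog was contrasted with vehicle. Of the analogs used at 100 nM, hPTH(1-31), PTH(1-36), bPTH(3-34) and hPTH(7-34) were contrasted with hPTH(1-34), and hPTH(7-34) with bPTH(3-34). bPTH(7-34), used at 1000 nM, was contrasted with vehicle only, apart from a contrast with hPTH(1-34) that served to choose genes for a score. p-values were two-sided and adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. A moderated F test covered the 6 contrasts with vehicle. Differences are log2 with the model's standard error (SE), and group values are means with the standard deviation (SD) of 3 arrays. Lists, tests, contrasts and the naming rule were fixed before the data were examined, apart from the alternatives and groups marked as chosen later.

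The 23 gene lists covered early response genes of cyclic AMP and CREB, cyclic AMP and G protein feedback, osteoclast-supporting cytokines, matrix remodelling enzymes, osteoblast matrix and differentiation, osteocytes, Wnt, TGF-beta and BMP, growth factors, inflammation, interferon-stimulated genes, the circadian clock, glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, vitamin D and calcium handling, the cell cycle, and markers of macrophages and osteoclasts, endothelium, cartilage, fat, muscle, and erythroid and lymphoid cells. Each was tested in each contrast with vehicle (138 tests) by limma's camera with a preset correlation of 0.01, adjusted over all 138. The tests were repeated with a correlation estimated for each list, and with fry, whose directional p asks whether the genes of a list move on balance 1 way and whose mixed p asks whether they change in either direction, neither against other genes. The count of members called over all genes is given beside the count adjusted over the list alone.

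Genes are named by rule. The rule took the 8 highest and 8 lowest changes of each contrast with vehicle and 5 and 5 of each contrast between analogs, among called genes whose 3 arrays lay beyond all 3 of the other group, without predicted genes, clones and small RNAs. It added a panel of 22 genes, of which 20 were measured, and up to 4 members of each list with the smallest adjusted p. A gene named outside the rule is marked as chosen after its values were seen.

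The response score of an array was the mean over a gene set of its log2 value minus the vehicle mean, signed by the direction in which the set was called. Sets were taken from an analog outside the pair compared. Scores were compared by exact two-sided permutation of 3 against 3 arrays, whose smallest p is 0.1, with a 95% interval from the spread pooled over the 7 groups. The effect of vehicle arrays common to 2 contrasts was simulated 50 times with independent values that shared only the vehicle. The replicate numbers were not used to pair arrays, since the labels say that cells were prepared independently for each replicate but not that a number marks 1 preparation across treatments.

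The limma calls were tested on simulated data, with no treatment effects and the spread of each gene as measured, and with a change added to 200 genes in each of 5 runs. In hPTH(1-34) against vehicle it recovered 46.4% of genes changed 1.5-fold, 86.4% of those changed 2-fold and 99.6% of those changed 4-fold, with 0 of the wrong sign, and 6.63% of its calls were false. With camera on simulated values, the 1 list shifted was called and 0 of the 22 others were. The alternatives tried were centring each array on its median, a further quantile normalization, leaving out genes under the median level, all transcript clusters, a fold threshold of 1.5, eBayes with trend and robust options, the replicate number as a block, leaving out each array in turn, and fitting only the 2 groups compared. Leaving out all arrays numbered 3, and scoring truncated analogs with genes chosen on other arrays, were added after the data were seen. Those genes were called in hPTH(1-34) against bPTH(7-34) (1827 genes, across doses) for the scores of bPTH(3-34) and hPTH(7-34), and in hPTH(1-34) against bPTH(3-34) (2068 genes) for that of bPTH(7-34). Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.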

Results

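Gene expression was measured in cultures of primary osteoblasts, the bone-forming cells, taken from the calvaria (skull vault) of C57BL/6J mouse pups 7 to 10 days old. The cells were at passage 2, were kept in differentiation medium from day 3 to day 10, and spent 24 h without serum before a 4 h treatment. The treatments were vehicle or 1 of 6 fragments of parathyroid hormone (PTH), the peptide that acts on osteoblasts through the receptor Pth1r, a receptor coupled to cyclic AMP. hPTH(1-34), hPTH(1-31) and PTH(1-36) keep the first residues of the hormone and are called intact analogs here. bPTH(3-34), hPTH(7-34) and the bovine (D-Trp12,Tyr34)-bPTH(7-34) amide, written bPTH(7-34) here, lack the first residues and are called truncated analogs. All were used at 100 nM except bPTH(7-34), which was used at 1000 nM. Each of the 7 groups had 3 arrays (Mouse Gene 2.0 ST, 100 ng of total RNA each), 21 in all.

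The arrays had similar distributions, with medians between 3.49 and 3.61 log2 units. Arrays of the same group correlated across genes at r = 0.990 to 0.993. The number of arrays limited the precision, and the 95% interval of a difference between 2 groups had a median half-width of 0.23 log2 units over the genes called in hPTH(1-31) or hPTH(1-34). An array gives no background value for a single gene here, so changes of genes with a low signal, such as Il6 with a vehicle mean of 2.65, may be understated. Each array measured a whole culture, and macrophage markers had high signals with vehicle, such as Lyz2 at 12.2, Cd68 at 11.3 and Csf1r at 10.2. The cell type in which a gene changed was therefore not determined.

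The first comparison asked what the reference fragment hPTH(1-34) did within 4 h. Dgat1, which encodes an enzyme of the last step of triacylglycerol synthesis (transcript cluster 17318502), rose from 5.76 ± 0.21 to 9.76 ± 0.07 log2 units (SD, n = 3), a 16.0-fold increase (adjusted p = 1.77e-14). Vdr, the vitamin D receptor (17321078), rose 14.2-fold (adjusted p = 3.44e-14). Tnfsf11, which encodes the osteoclast-forming cytokine RANKL (17308817), rose 8.67-fold, from 4.24 ± 0.05 to 7.35 ± 0.13 (SD, n = 3; adjusted p = 2.41e-09), while its decoy receptor Tnfrsf11b (osteoprotegerin) fell by 1.36 ± 0.15 (log2, SE). Lgr5, a receptor for the Wnt-enhancing R-spondins (17245059), was 4.22-fold lower than with vehicle, at 7.23 ± 0.06 against 9.30 ± 0.01 (SD, n = 3; adjusted p = 1.09e-12).

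The other genes with the highest changes were the nuclear receptors Nr4a3 (+3.60 ± 0.19, log2, SE) and Nr4a2 (+2.79 ± 0.15), both early targets of cyclic AMP, Lrrc32 (+2.95 ± 0.10), which tethers latent TGF-beta at the cell surface, the chemokine Cxcl14 (+2.69 ± 0.13), and Smim3 (+2.64 ± 0.12). The other genes with the lowest changes were Dusp27 (-2.09 ± 0.20), the bone morphogenetic proteins Bmp4 (-1.97 ± 0.15) and Bmp2 (-1.73 ± 0.13), the vasodilator peptide Adm (-1.85 ± 0.19), the Wnt receptor Fzd5 (-1.77 ± 0.08), the hyaluronan-degrading Cemip (-1.77 ± 0.11) and the R-spondin Rspo3 (-1.67 ± 0.08). Of 22180 genes tested, 865 rose and 1052 fell, 1917 in all. Of these, 783 changed at least 1.5-fold and 251 at least 2-fold, 181 of them up and 70 down. For 1904 of the 1917 the 3 treated arrays lay beyond all 3 vehicle arrays. Over all genes that share was 23.4%, where chance gives 10%.

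Among the panel of PTH-responsive and bone genes chosen in advance, Il6 (+2.37 ± 0.25), the nuclear receptor Nr4a1 (+1.71 ± 0.16), the transcriptional regulators Cited1 (+1.11 ± 0.19) and Crem (+1.09 ± 0.12), the prostaglandin synthase Ptgs2 (+0.99 ± 0.24) and Fos (+0.68 ± 0.14) rose with hPTH(1-34). The receptor Pth1r fell by 1.10 ± 0.12, and Sp7, the osteoblast transcription factor osterix, fell by 0.56 ± 0.13. The panel genes not called were Rgs2 (+0.33, adjusted p = 0.0839), the collagenase Mmp13 (-0.01), the Wnt inhibitors Sost (+0.24) and Dkk1 (-0.20), Igf1 (+0.10), osteocalcin Bglap (-0.09), Col1a1 (-0.02 ± 0.06) and Saa3 (+0.37). With vehicle, Sost (3.51), Dkk1 (3.57) and Bglap (3.73) lay near the array medians of 3.49 to 3.61. A change in these 3 genes, above all a fall, could therefore be missed with any analog. Wnt4 was at +0.82 (adjusted p = 0.0427), a call lost when any 1 of the 6 arrays was left out (adjusted p up to 0.129). The call of Sp7 was lost without vehicle replicate 1 or hPTH(1-34) replicate 3 (adjusted p up to 0.0704), and that of Ptgs2 without hPTH(1-34) replicate 3 (adjusted p = 0.0570).

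Early response genes of cyclic AMP and its transcription factor CREB formed the list with the clearest change. Of 28 measured, 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median change of +0.97, and Pde10a, a phosphodiesterase that breaks down cyclic AMP (+2.05 ± 0.10), and Fosl2 (+0.99 ± 0.07) were among them (camera adjusted p = 6.33e-24, and adjusted p = 7.10e-05 with an estimated correlation). Of 30 genes of cyclic AMP and G protein feedback, 9 rose and 2 fell (10 and 6 adjusted over the list alone). The phosphodiesterase Pde3b (+1.49 ± 0.11), the receptor activity modifying protein Ramp3 (+1.86 ± 0.15) and Gprc5a (+1.81 ± 0.15) rose, and the list passed the test upward (adjusted p = 0.0191) but had adjusted p = 0.0823 with an estimated correlation. The list of inflammatory and acute phase genes also passed, with 15 of 34 higher and 0 lower (18 and 0 adjusted over the list alone), a median of +0.43, adjusted p = 1.82e-13 and adjusted p = 0.00477 with an estimated correlation. Among its members the neutrophil chemokine Cxcl5 (+1.25 ± 0.13), Tnf (+1.40 ± 0.16) and the hyaluronan-binding Tnfaip6 (+1.10 ± 0.14) rose. None of the 24 macrophage and osteoclast markers was called (0 adjusted over the list alone; list adjusted p = 0.926), with Csf1r at -0.09 and Mrc1 at +0.07.

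Of 20 genes of vitamin D, calcium and phosphate handling, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with the calcium pump Atp2b4 (+0.60 ± 0.09) and the glycoprotein hormone Stc1 (+0.72 ± 0.15) beside Vdr, and the list had adjusted p = 0.00975 upward, but adjusted p = 0.0823 with an estimated correlation. The cell cycle list passed downward, with 7 of 35 called down and 0 up (13 and 0 adjusted over the list alone), with a median of -0.24 (adjusted p = 1.72e-06, but adjusted p = 0.111 with an estimated correlation). The mitotic kinase Bub1 was at -0.35 ± 0.09 (adjusted p = 0.0169), and its call was lost without vehicle replicate 2 or 3 or without hPTH(1-34) replicate 1 or 3 (adjusted p up to 0.0811).

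None of the remaining lists was called by camera. Of 50 Wnt pathway genes 11 rose and 11 fell (11 and 12 adjusted over the list alone; list adjusted p = 0.590), the R-spondin Rspo2 (-1.55 ± 0.10) among the latter. Of 45 TGF-beta and BMP genes 6 rose and 11 fell (9 and 15 adjusted over the list alone; list adjusted p = 0.640), with the BMP antagonist Grem1 up (+2.04 ± 0.09) and the BMP target Id3 down (-0.90 ± 0.09). Of 15 osteoclast-supporting cytokines 4 rose and 2 fell (4 and 4 adjusted over the list alone; list adjusted p = 0.805), among them Il34, a ligand of Csf1r, which fell by 1.00 ± 0.10. Of 26 matrix remodelling enzymes 5 rose and 3 fell (7 and 4 adjusted over the list alone; list adjusted p = 0.264). The hyaluronan synthase Has2 (+1.89 ± 0.09), the aggrecan-cleaving Adamts4 (+1.79 ± 0.12) and the urokinase receptor Plaur (+1.67 ± 0.15) rose, and Adamts5 fell by 1.00 ± 0.08. Of 28 osteoblast matrix and differentiation genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.746), with the alkaline phosphatase gene Alpl at +0.56 ± 0.10. Of 15 osteocyte genes 2 rose and 0 fell (3 and 0 adjusted over the list alone; list adjusted p = 0.198), namely Pdpn (+0.95 ± 0.09) and the gap junction gene Gja1 (+0.82 ± 0.09).

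Of 40 IGF, FGF and other growth factor genes 6 rose and 4 fell (7 and 7 adjusted over the list alone; list adjusted p = 0.991), with the growth factor receptors Pdgfrb (-0.86 ± 0.09) and Egfr (-0.71 ± 0.08) down and Igfbp5 (+0.53 ± 0.07) up. Of 17 circadian clock genes 4 rose and 3 fell (7 and 5 adjusted over the list alone; list adjusted p = 0.413), with Arntl (+0.93 ± 0.10) and Nfil3 (+1.10 ± 0.12) up and Per3 (-1.03 ± 0.12) down. Of 26 glycolysis and glucose uptake genes 4 rose and 2 fell (5 and 4 adjusted over the list alone; list adjusted p = 0.392), with the lactate transporter Slc16a1 at +1.99 ± 0.12 and the glucose transporter Slc2a1 at +0.59 ± 0.13. Of 19 cholesterol synthesis genes 4 rose and 4 fell (6 and 5 adjusted over the list alone; list adjusted p = 0.718), with Pmvk at +2.07 ± 0.12. Of 29 unfolded protein and amino acid stress genes 4 rose and 0 fell (5 and 2 adjusted over the list alone; list adjusted p = 0.360), with the mTOR inhibitor Ddit4 at +0.86 ± 0.10 and the amino acid transporter Slc7a5 at +1.00 ± 0.12. Of 26 interferon-stimulated genes 1 rose and 1 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.746).

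Lists for other cell types gave few calls. Of 15 endothelial markers 0 rose and 2 fell (0 and 2 adjusted over the list alone; list adjusted p = 0.728), and of 16 chondrocyte markers 0 rose and 1 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.728), which was Sox6 (-0.93 ± 0.11). Of 13 adipocyte markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.964), Dgat2 (+0.83 ± 0.14), the other triacylglycerol-forming enzyme, and the adipocyte regulator Pparg (-0.61 ± 0.12). Of 16 muscle and smooth muscle markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.590), with the actin-binding calponin Cnn1 at +2.10 ± 0.08. None of 7 erythroid and lymphoid markers was called (0 adjusted over the list alone; list adjusted p = 0.978). Median and mean differed in sign for several lists. The median was below 0 and the mean above it for cyclic AMP and G protein feedback (-0.0017 and +0.26), osteoclast-supporting cytokines (-0.07 and +0.29), cholesterol synthesis (-0.02 and +0.11), the unfolded protein list (-0.01 and +0.06), macrophage markers (-0.005 and +0.0029), each with the test upward, and adipocyte markers (-0.09 and +0.0018), with the test downward. The median was above 0 and the mean below it for the Wnt (+0.08 and -0.09), TGF-beta and BMP (+0.01 and -0.07) and endothelial lists (+0.0033 and -0.07), with the test downward, and for the erythroid and lymphoid list (+0.14 and -0.01), with the test upward.

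**Figure D1:**
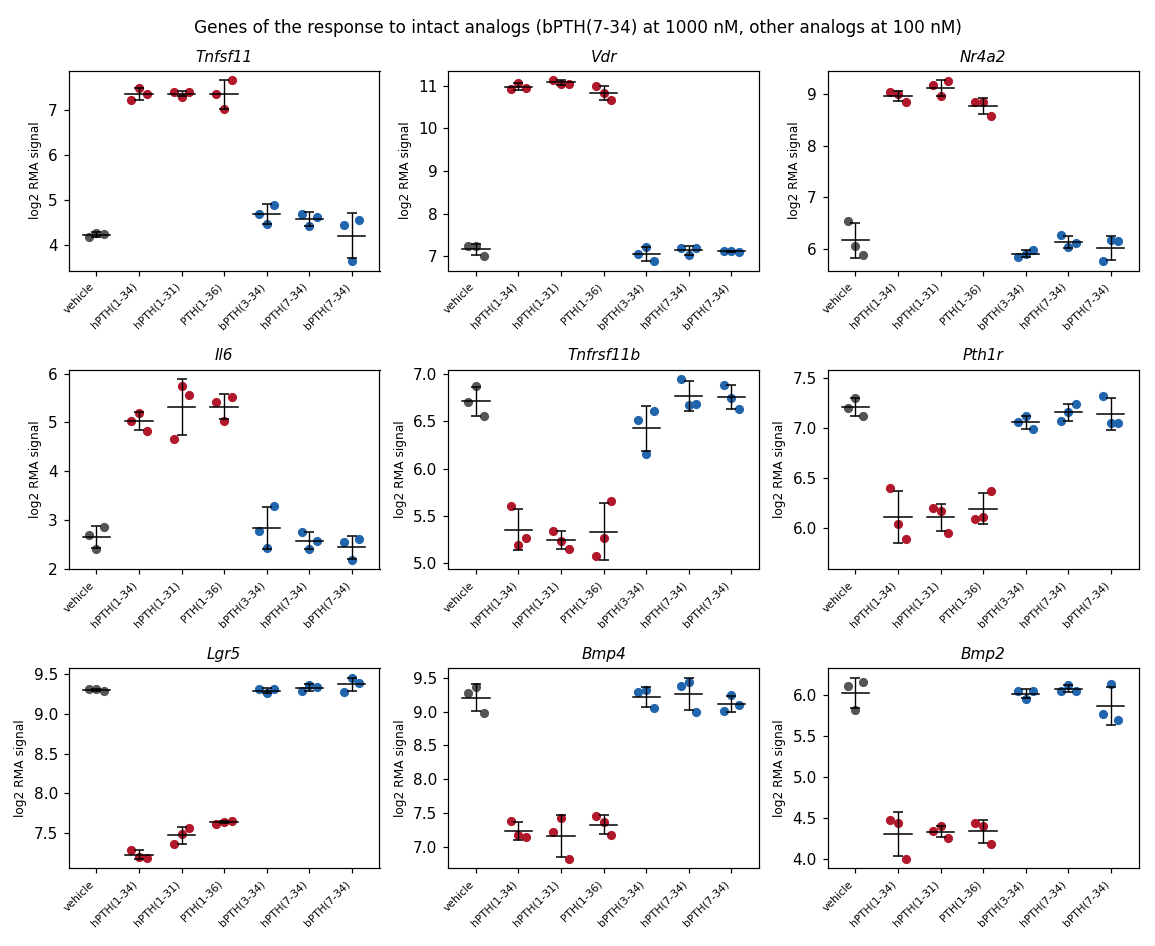
Log2 RMA signal of selected genes in each array, by treatment (points, single arrays; bars, mean and SD of 3 arrays). Tnfsf11, for example, stood at 4.24 with vehicle and 7.35 with hPTH(1-34), and for these genes the intact analogs lay apart from vehicle and the truncated analogs.

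The next comparisons asked whether intact analogs that end at other residues gave another response. With hPTH(1-31), a shorter fragment known to raise cyclic AMP, the largest increases were in Dgat1 (+3.98 ± 0.10, log2, SE), Nr4a3 (+3.93 ± 0.19), Vdr (+3.92 ± 0.10), Lrrc32 (+3.14 ± 0.10), Tnfsf11 (+3.12 ± 0.19), Nr4a2 (+2.95 ± 0.15), Smim3 (+2.86 ± 0.12) and Cbarp (+2.80 ± 0.16), a regulator of calcium channels. The largest decreases were in Bmp4 (-2.05 ± 0.15), Dusp27 (-1.88 ± 0.20), Fzd5 (-1.85 ± 0.08), Lgr5 (-1.83 ± 0.07), Rspo3 (-1.83 ± 0.08), Cemip (-1.70 ± 0.11), Bmp2 (-1.70 ± 0.13) and the kinase Map2k6 (-1.68 ± 0.12). Against vehicle 1930 genes were called, 971 up and 959 down, 805 of them at least 1.5-fold. Il6 (+2.67 ± 0.25) and Pth1r (-1.10 ± 0.12) changed as well, while Mmp13 (+0.07) and Sost (+0.07) were not called. Rgs2, a brake on G protein signals, was at +0.45 (adjusted p = 0.0160), a call lost without vehicle replicate 1 or 3 or hPTH(1-31) replicate 1 (adjusted p up to 0.0828).

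With PTH(1-36), which is longer at its end, the largest increases were in Dgat1 (+3.93 ± 0.10), Nr4a3 (+3.70 ± 0.19), Vdr (+3.67 ± 0.10), Tnfsf11 (+3.11 ± 0.19), Smim3 (+2.81 ± 0.12), Lrrc32 (+2.79 ± 0.10), Il6 (+2.67 ± 0.25) and Cbarp (+2.66 ± 0.16). The largest decreases were in Dusp27 (-2.15 ± 0.20), Bmp4 (-1.87 ± 0.15), Adm (-1.70 ± 0.19), Bmp2 (-1.69 ± 0.13), Lgr5 (-1.67 ± 0.07), Mtss2 (-1.56 ± 0.14), Cemip (-1.56 ± 0.11) and Fzd5 (-1.55 ± 0.08). Against vehicle 1603 genes were called, 817 up and 786 down, 701 of them at least 1.5-fold. Pth1r fell by 1.02 ± 0.12, while Fos (+0.43, adjusted p = 0.0734), Mmp13 (+0.19) and Sost (+0.04) were not called.

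Of the 5 lists called with hPTH(1-34), 4 were also called with both of these analogs, and the cell cycle list only with hPTH(1-31). Cyclic AMP and CREB early response genes rose, 21 up and 1 down of 28 with hPTH(1-31) (22 and 3 adjusted over the list alone) and 19 up and 3 down with PTH(1-36) (21 and 3 adjusted over the list alone), with adjusted p = 7.10e-05 and 7.47e-05 with an estimated correlation. Pde10a was at +2.08 ± 0.10 and +1.79 ± 0.10. Inflammatory and acute phase genes passed upward, 15 up and 0 down of 34 with hPTH(1-31) (18 and 0 adjusted over the list alone) and 10 up and 0 down with PTH(1-36) (12 and 0 adjusted over the list alone), with adjusted p = 0.00900 and 0.0260 with an estimated correlation. Tnf was at +1.48 ± 0.16 and +1.22 ± 0.16. Cyclic AMP and G protein feedback genes passed upward with both (adjusted p = 0.0183 and 0.00216), with 11 up and 3 down for hPTH(1-31), where adjusted p = 0.0823 with an estimated correlation, and 11 up and 2 down for PTH(1-36), where adjusted p = 0.0280 with an estimated correlation (12 and 6, and 11 and 3, adjusted over the list alone). For hPTH(1-31) the median of this list was -0.02 and its mean +0.26. Vitamin D, calcium and phosphate genes passed upward, 5 up and 0 down of 20 for each (5 and 6 up adjusted over the list alone; adjusted p = 0.0281 and 0.0231), but had adjusted p = 0.130 and 0.116 with an estimated correlation.

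Cell cycle genes passed downward with hPTH(1-31), with 2 of 35 down (0 adjusted over the list alone; adjusted p = 0.0279, but adjusted p = 0.497 with an estimated correlation), and not with PTH(1-36) (2 down, and 2 adjusted over the list alone; adjusted p = 0.0749). Cholesterol synthesis genes passed upward with PTH(1-36), with 6 of 19 up and 0 down (7 and 3 adjusted over the list alone; adjusted p = 0.0191, but adjusted p = 0.463 with an estimated correlation), among them Pmvk (+2.05 ± 0.12), Hsd17b7 (+0.83 ± 0.08), Cyp51 (+0.55 ± 0.09) and Hmgcs1 (+0.32 ± 0.07). The difference between analogs was not tested for lists. In all, 1171 genes were called with each of the 3 intact analogs, 622 higher and 549 lower, every one in the same direction with all 3, and 2603 with at least 1 of them.

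All contrasts with vehicle used the same 3 vehicle arrays, so part of what they share may come from those arrays. hPTH(1-34) and hPTH(1-31) shared 738 genes called higher and 733 called lower, where independent lists would share 37.9 and 45.5. Their changes correlated across genes, which are not independent replicates, at r = 0.84, where simulated data with only the vehicle in common gave r = 0.50. The covariance was 0.0750 against 0.0150 in the simulation. hPTH(1-34) and PTH(1-36) shared 640 higher and 608 lower, where independent lists would share 31.9 and 37.3, with r = 0.81 and a covariance of 0.0686. hPTH(1-31) and PTH(1-36) shared 690 higher and 609 lower, where independent lists would share 35.8 and 34.0, with r = 0.82 and a covariance of 0.0704.

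The direct contrasts between intact analogs, which need no vehicle, called almost nothing. For hPTH(1-31) against hPTH(1-34) limma called 0 genes, with 994 at an unadjusted p under 0.05 where chance gives 1109. For 91.1% of the 2376 genes called with either analog against vehicle, the 95% interval of the difference lay within 1.5-fold. For PTH(1-36) against hPTH(1-34) limma called 1 gene, Prg4, which encodes the joint lubricant lubricin. Prg4 stood at 5.99 with vehicle, 8.29 ± 0.14 with hPTH(1-34) and 7.28 ± 0.34 with PTH(1-36) (SD, n = 3), a difference of -1.01 ± 0.13 (SE; adjusted p = 0.0144), with every PTH(1-36) array below every hPTH(1-34) array. That call was lost without hPTH(1-34) replicate 1 or 2 or PTH(1-36) replicate 2 or 3, each of which left 0 genes (adjusted p up to 0.201), and leaving out hPTH(1-34) replicate 3 gave 3 genes. In this contrast 1423 genes had an unadjusted p under 0.05, and 88.9% of the 2272 genes called with either analog against vehicle had an interval within 1.5-fold.

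A response score, the mean signed log2 change over genes chosen on another analog, compared the strength of the responses. Over 1930 genes called with hPTH(1-31), hPTH(1-34) scored 0.61 above vehicle (95% interval 0.59 to 0.63; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). The same vehicle arrays entered the choice of those genes, which biases this score upward, and the interval does not cover that bias. Over 1603 genes called with PTH(1-36), hPTH(1-31) scored 0.673 ± 0.021 and hPTH(1-34) 0.653 ± 0.013 (SD, n = 3), a difference of 0.020 (95% interval -0.0053 to 0.046; exact two-sided permutation p = 0.2). That difference was 0.029 without hPTH(1-31) replicate 2, with an interval above 0, 0.0088 without hPTH(1-31) replicate 3, and 0.0020 without all arrays numbered 3. Over the 1930 genes, PTH(1-36) scored 0.565 ± 0.0077 and hPTH(1-34) 0.612 ± 0.018 (SD, n = 3), 92.4% of it, with a difference of -0.047 (95% interval -0.066 to -0.028; exact two-sided permutation p = 0.1). The bias from the vehicle arrays is common to both scores, so it leaves their difference unchanged but may raise the percentage.

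**Figure D2:**
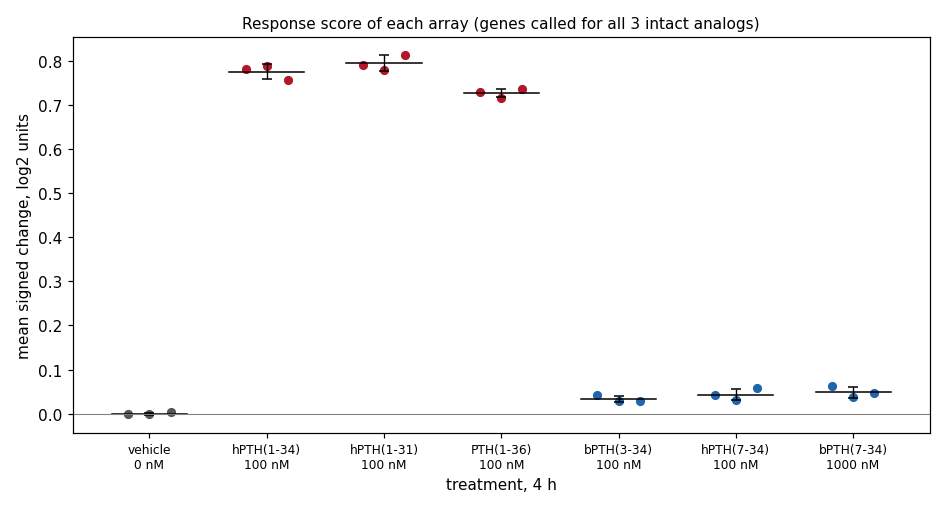
Response score of each array in log2 units, the mean over the 1171 genes called with all 3 intact analogs of the change from the vehicle mean, signed by direction (points, arrays; bars, mean and SD of 3). The intact analogs sat between 0.717 and 0.814 and the truncated analogs between 0.029 and 0.062. The genes were chosen on the intact and vehicle arrays, which favours the intact analogs. The use of the vehicle arrays in that choice also biases the truncated scores upward.

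bPTH(3-34), which lacks the first residues, was included to ask what remains of the response without them. Several genes that led the hPTH(1-34) response lay near the vehicle level. Dgat1 was at +0.14, Vdr at -0.11, Tnfsf11 at +0.45 ± 0.19 and Il6 at +0.17 ± 0.25, none of them called. For Tnfsf11 the bPTH(3-34) arrays (4.70, 4.47 and 4.90) were all above the highest vehicle array (4.28), so a small rise is not excluded. limma called 0 genes against vehicle, with 1313 at an unadjusted p under 0.05 where chance gives 1109, and the smallest adjusted p was 0.446. No list was called by camera, and no list member was called. Against hPTH(1-34) at the same dose 2068 genes were called, 1194 higher and 874 lower with bPTH(3-34). Lgr5 (+2.07 ± 0.07), Dusp27 (+2.04 ± 0.20), Bmp4 (+1.98 ± 0.15), Adm (+1.90 ± 0.19) and Fzd5 (+1.84 ± 0.08) were higher, and Vdr (-3.93 ± 0.10), Dgat1 (-3.86 ± 0.10), Nr4a3 (-3.42 ± 0.19), Nr4a2 (-3.04 ± 0.15) and Lrrc32 (-2.85 ± 0.10) were lower. The higher genes made up 57.7% of those called, 71.6% when each array was centred on its median and 53.1% after quantile normalization.

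Over the 1917 genes called with hPTH(1-34), bPTH(3-34) scored 0.040 above vehicle (95% interval 0.019 to 0.061; exact two-sided permutation p = 0.1, the smallest possible). The same vehicle arrays entered the choice of those genes, which biases this score upward. With 1827 genes chosen on neither the vehicle nor the bPTH(3-34) arrays, a choice made after the first score was seen, the difference was -0.0077 (95% interval -0.029 to 0.014; exact two-sided permutation p = 0.4).

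hPTH(7-34), a fragment known as a blocker of the PTH receptor, left several leading genes of the hPTH(1-34) response near vehicle, with Dgat1 at +0.17, Vdr at -0.02, Tnfsf11 at +0.35 ± 0.19, Nr4a2 at -0.03 ± 0.15 and Il6 at -0.08 ± 0.25, none called. The Tnfsf11 arrays (4.70, 4.42 and 4.63) were all above the highest vehicle array (4.28), so a small rise is not excluded. A small set of innate immune genes rose with hPTH(7-34). Acod1, the itaconate-forming enzyme of activated macrophages, rose by 2.00 ± 0.27 (log2, SE), from 4.40 ± 0.45 to 6.40 ± 0.72 (SD, n = 3; adjusted p = 0.00284), the interferon-inducible chemokine Cxcl10 by 1.60 ± 0.24, the C-type lectin Clec4e by 1.45 ± 0.18 and the receptor Gpr84 by 1.37 ± 0.21. Ccl2 (+1.16 ± 0.19), Tnip3 (+1.09 ± 0.14), Ccl12 (+1.02 ± 0.15), the NF-kappaB inhibitor Nfkbie (+0.98 ± 0.13), Tnf (+0.95 ± 0.16) and Tlr2 (+0.86 ± 0.11) rose too. The developmental genes Hoxa7 (-0.72 ± 0.11), Nrarp (-0.58 ± 0.09) and Gbx2 (-0.58 ± 0.09) fell. The other calls, Gm8995 (+1.10), Gm12250 (+1.05) and Pstpip2 (+0.50), are named although the rule left them out, chosen after their values were seen.

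hPTH(7-34) replicate 3 had the highest value of its group for 12 of the 13 higher genes, a count made after the values were seen, with Acod1 at 7.22 against 5.90 and 6.08. The median change of the 13 genes from the vehicle mean was 0.90, 0.98 and 1.30 in replicates 1, 2 and 3. In all limma called 16 genes, 13 higher and 3 lower, with 1817 at an unadjusted p under 0.05, and in all 16 the groups did not overlap. Over all genes that share was 12.3%, where chance gives 10%. The count was 6 without vehicle replicate 3, 24 without vehicle replicate 2, and 0 when only these 2 groups were fitted or when all arrays numbered 3 were left out, the last an alternative chosen after the data were seen. The calls of Acod1, Clec4e, Tnip3, Nfkbie, Tlr2 and Gm8995 were kept without any 1 of the 6 arrays. Those of Cxcl10 and Gpr84 were lost without vehicle replicate 3 (adjusted p = 0.0801 for both), and that of Ccl2 without vehicle replicate 1 or 3 (adjusted p up to 0.0877). Ccl12 lost its call without vehicle replicate 1 or 3 or hPTH(7-34) replicate 3 (adjusted p up to 0.0801), Tnf without vehicle replicate 1 or 3 or hPTH(7-34) replicate 2 or 3 (adjusted p up to 0.248), Gm12250 without any 1 array but vehicle replicate 2, and Pstpip2 without any 1 array (adjusted p up to 0.280). Hoxa7, Nrarp and Gbx2 lost their calls without vehicle replicate 3, and without hPTH(7-34) replicate 1, 2 and 3 in that order (adjusted p up to 0.0846).

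Inflammatory and acute phase genes as a list passed upward with hPTH(7-34), with 4 of 34 up and 0 down (13 and 0 adjusted over the list alone), a median of +0.31, adjusted p = 1.82e-13, and adjusted p = 0.00477 with an estimated correlation. Of 26 interferon-stimulated genes 0 were called over all genes (8 up and 0 down adjusted over the list alone), among them Parp14 (+0.61), Ifit1 (+0.58), Iigp1 (+0.54) and Ddx60 (+0.44). The list had a median of +0.35 and passed upward (adjusted p = 1.82e-13), but had adjusted p = 0.225 with an estimated correlation. Of 24 macrophage and osteoclast markers 0 were called (0 adjusted over the list alone), and the list had a median of +0.14 and adjusted p = 4.21e-04, but adjusted p = 0.414 with an estimated correlation. Ptprc was at +0.26, C1qb at +0.24 and Cd14 at +0.36, while the abundant Mrc1 (10.8 with vehicle) and Csf1r (10.2 with vehicle) were at +0.11 and +0.09. Cyclic AMP and CREB early response genes had 0 of 28 called (0 adjusted over the list alone), a median of +0.12 and adjusted p = 0.00105, but adjusted p = 0.0988 with an estimated correlation, with Dio2 at +0.61 and Nr4a3 at +0.51.

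**Figure D3:**
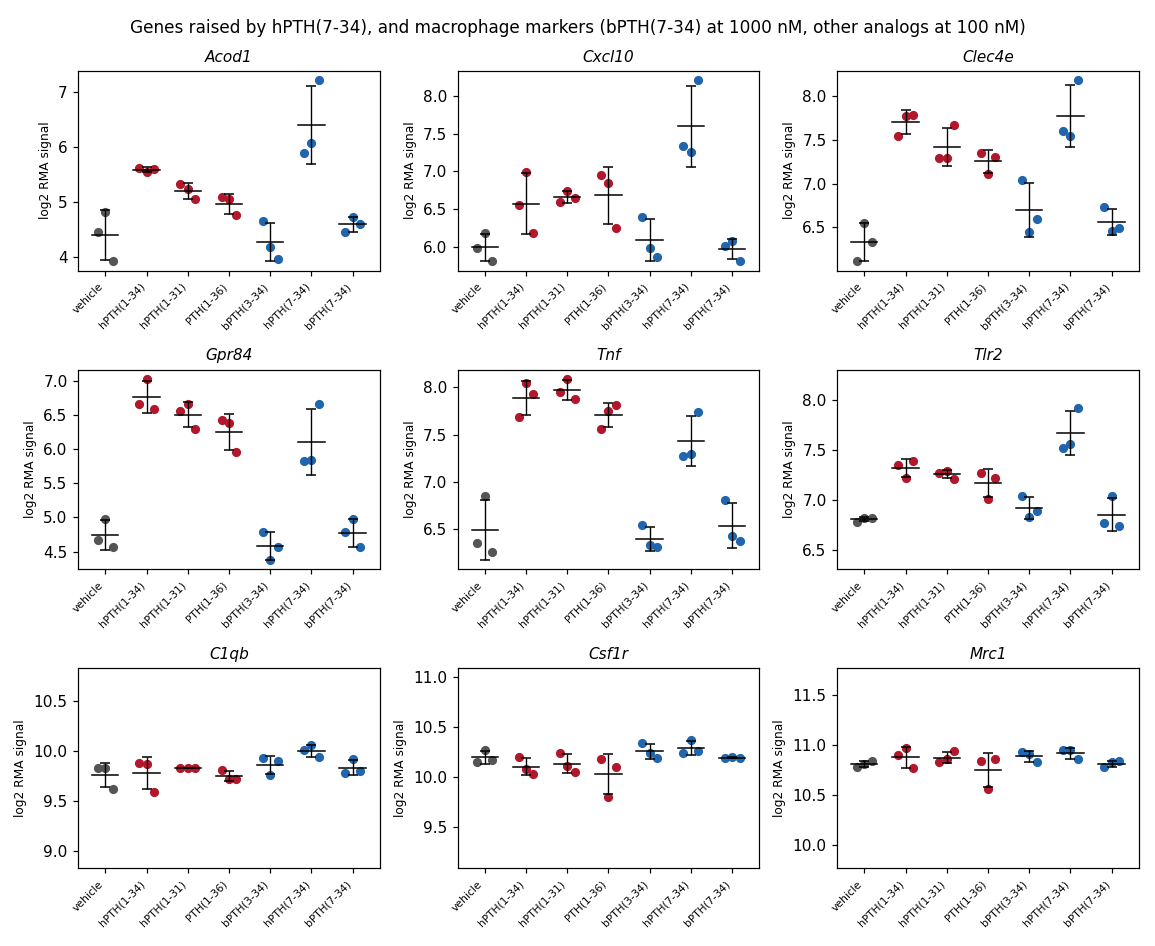
Log2 RMA signal of innate immune genes and macrophage markers in each array, by treatment (points, single arrays; bars, mean and SD of 3 arrays). Acod1 rose by 2.00 with hPTH(7-34), while the macrophage markers C1qb, Csf1r and Mrc1 were at +0.24, +0.09 and +0.11.

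Of the 13 genes higher with hPTH(7-34), 9 were also called higher with hPTH(1-34), 8 with hPTH(1-31) and 8 with PTH(1-36), and 0 with either bovine peptide. hPTH(1-34) and hPTH(7-34) shared 9 genes called higher and 1 called lower, where independent lists would share 0.507 and 0.142, and the vehicle arrays they have in common can account for part of that. Their changes correlated across genes at r = 0.25, where simulated data gave r = 0.50, with a covariance of 0.0145 against 0.0150. The simulation held no treatment effects. Those of hPTH(1-34) widen the spread of its changes and lower r, so only the covariances can be compared here. Directly against hPTH(1-34), 8 of the 16 genes called with hPTH(7-34) were called, 4 higher and 4 lower. hPTH(7-34) gave higher Cxcl10 (+1.02 ± 0.24, adjusted p = 0.00884), a call lost without hPTH(1-34) replicate 3 or hPTH(7-34) replicate 3 (adjusted p up to 0.0560), and lower Ccl12 (-0.78 ± 0.15, adjusted p = 0.00224). The others, named after their values were seen, were Gm12250 (+1.04 ± 0.19), Gm8995 (+0.73 ± 0.14), Pstpip2 (+0.34 ± 0.09), Gbx2 (-0.58 ± 0.09), Nrarp (-0.48 ± 0.09) and Hoxa7 (-0.36 ± 0.11). Pstpip2 lost its call without hPTH(1-34) replicate 2 or 3 or hPTH(7-34) replicate 3 (adjusted p up to 0.0989). Hoxa7 lost its call without any 1 array but hPTH(1-34) replicate 2 (adjusted p up to 0.174), and when each array was centred on its median (adjusted p = 0.122). Acod1 was at +0.81 ± 0.27 (adjusted p = 0.0611, and called without hPTH(7-34) replicate 1) and Gpr84 at -0.65 ± 0.21 (adjusted p = 0.0501, and called without hPTH(7-34) replicate 3).

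Against hPTH(1-34) 2409 genes were called in all, 1478 higher and 931 lower with hPTH(7-34), 61.4% of them higher, 79.2% when each array was centred on its median and 53.7% after quantile normalization. Dusp27 (+2.13 ± 0.20), Lgr5 (+2.11 ± 0.07), Bmp4 (+2.03 ± 0.15), Adm (+1.98 ± 0.19) and Bmp2 (+1.78 ± 0.13) were higher, and Vdr (-3.85 ± 0.10), Dgat1 (-3.82 ± 0.10), Nr4a3 (-3.08 ± 0.19), Lrrc32 (-2.95 ± 0.10) and Nr4a2 (-2.81 ± 0.15) were lower. Over 1917 genes called with hPTH(1-34), hPTH(7-34) scored 0.045 above vehicle (95% interval 0.025 to 0.066; exact two-sided permutation p = 0.1, the smallest possible), with the same upward bias. With genes chosen on neither the vehicle nor the hPTH(7-34) arrays the difference was 0.0010 (95% interval -0.020 to 0.023; exact two-sided permutation p = 0.9).

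hPTH(7-34) was also compared with bPTH(3-34), both at 100 nM. Acod1 (+2.13 ± 0.27), Gpr84 (+1.53 ± 0.21), Cxcl10 (+1.51 ± 0.24), Tnip3 (+1.15 ± 0.14) and Clec4e (+1.08 ± 0.18) were higher with hPTH(7-34). The other genes called, Nlrp1c-ps (+1.36), Ccl12 (+1.06), Tnf (+1.03), Nfkbie (+0.77), Tlr2 (+0.75) and Irf1 (+0.59), were also higher, and are named after their values were seen. limma called 11 genes, 11 higher and 0 lower, with 1124 at an unadjusted p under 0.05. The calls of Acod1 and Tnip3 were kept without any 1 of the 6 arrays. The count was 2 without bPTH(3-34) replicate 2, 4 without bPTH(3-34) replicate 3, 4 without hPTH(7-34) replicate 3, and 0 when only these 2 groups were fitted or when all arrays numbered 3 were left out. Every call but those of Acod1 and Tnip3 was lost without bPTH(3-34) replicate 2. Cxcl10, Clec4e, Tnf, Nfkbie, Tlr2, Irf1 and Nlrp1c-ps were also lost without bPTH(3-34) replicate 3 or hPTH(7-34) replicate 3, and Ccl12 without bPTH(3-34) replicate 1 or hPTH(7-34) replicate 3. Nfkbie and Irf1 were lost without bPTH(3-34) replicate 1 or hPTH(7-34) replicate 1 as well, Nlrp1c-ps without hPTH(7-34) replicate 1 or 2, and Irf1 without hPTH(7-34) replicate 2 (adjusted p up to 0.270).

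bPTH(7-34) was used at 1000 nM, a dose that differs from the others, so its values stand beside theirs without a direct test. Dgat1 was at +0.25, Vdr at -0.05, Tnfsf11 at -0.03 ± 0.19, Il6 at -0.21 ± 0.25 and Lgr5 at +0.07 against vehicle, none of them called. Nr4a3 was at +0.51 ± 0.19 (limma adjusted p = 0.881) and Nr4a2 at -0.14 ± 0.15, neither called. The genes that hPTH(7-34) raised were at +0.19 for Acod1, -0.02 for Cxcl10, +0.05 for Tnf and +0.36 for Ccl2, also not called. limma called 0 genes, with 1151 at an unadjusted p under 0.05 where chance gives 1109, and the smallest adjusted p was 0.272. Of 35 cell cycle genes 0 were called (0 adjusted over the list alone), and the list passed downward with a median of -0.08 (adjusted p = 5.75e-04, but adjusted p = 0.260 with an estimated correlation). Over 1917 genes the score was 0.059 above vehicle (95% interval 0.038 to 0.080; exact two-sided permutation p = 0.1, the smallest possible), with the bias described for bPTH(3-34). Over 2068 genes chosen on neither the vehicle nor the bPTH(7-34) arrays the difference was 0.0087 (95% interval -0.015 to 0.032; exact two-sided permutation p = 0.4).

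**Figure D4:**
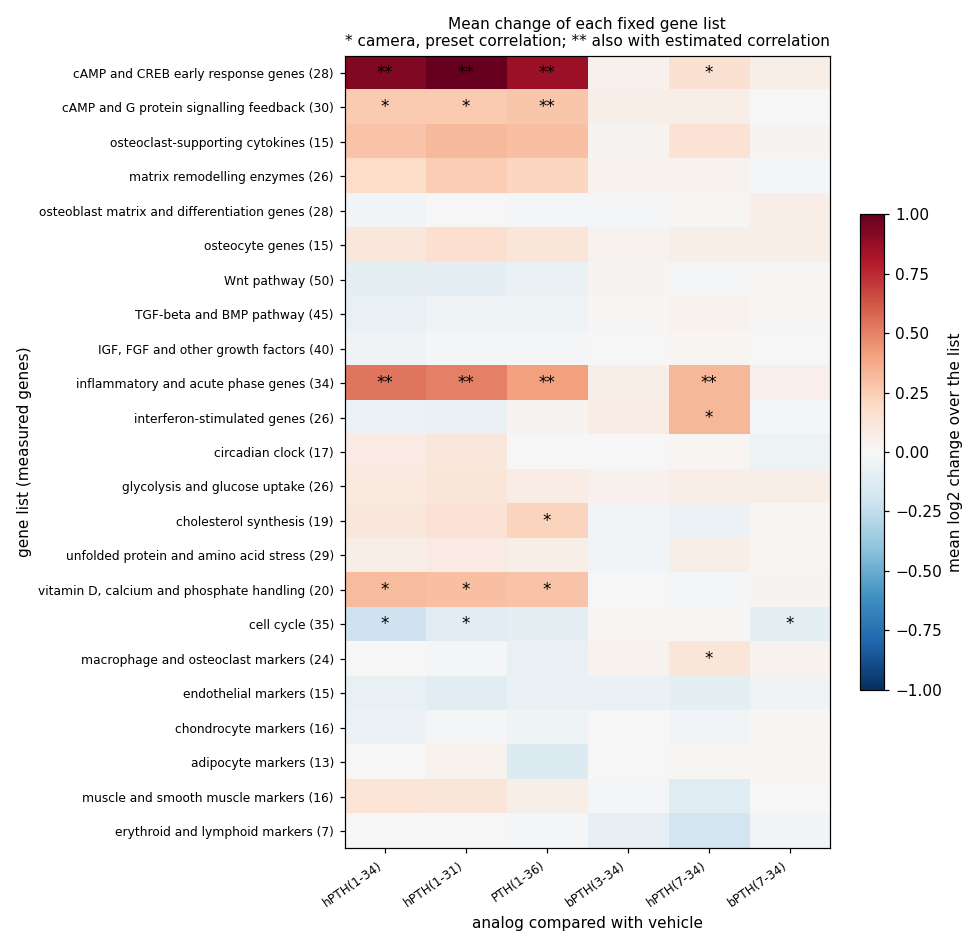
Mean log2 change of each gene list with each analog against vehicle (colour scale from -1 to +1; measured genes of each list in parentheses). One star marks lists called by camera with its preset correlation and a pair of stars those also called with an estimated correlation, 20 and 8 of 138 tests.

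Across all 7 groups the limma F test called 2717 of 22180 genes at an adjusted p under 0.05.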

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

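The tests weighed in this part were chosen after the result was seen, except the quantile normalization of the response score; leaving out each array in turn was chosen before the data were examined, but its use as a test of a pattern came afterwards. Transcript clusters that carry no symbol or several were not part of the comparisons, and some of them also passed the test against vehicle. Of 17824 such clusters, 60 were called with hPTH(1-34), 62 with hPTH(1-31), 52 with PTH(1-36) and 2 with hPTH(7-34), and limma called 0 with bPTH(3-34) and bPTH(7-34), with 1110 and 966 at an unadjusted p under 0.05. The called cluster with the largest change for each intact analog was 17212211, at +3.87 ± 0.11 (log2, SE) with hPTH(1-34), +3.76 with hPTH(1-31) and +3.53 with PTH(1-36), and no gene can be named for it from the annotation at hand.

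The first pattern weighed is the rise of 13 mostly innate immune genes with hPTH(7-34), whose median was +1.09 (log2). More macrophages in those cultures would raise abundant macrophage markers by about as much. The 17 markers with a vehicle mean over 7, such as Mrc1 at 10.8 and Csf1r at 10.2, had a median of +0.15 (SD over markers 0.07). That argues against more macrophages as the main cause. All 17 markers were above 0 (lowest +0.09), so a small part is not excluded. Against the same vehicle arrays their median was +0.08 with bPTH(3-34) and +0.04 with bPTH(7-34). With hPTH(1-34) it did not move, and it was -0.03 with hPTH(1-31) and -0.11 with PTH(1-36). The 13 genes were picked for their rise in these arrays, which inflates their median. An effect common to every fragment without its first residues is also argued against, since the median of the same 13 genes was at most +0.09 with a bovine truncated peptide. Those peptides differ in species sequence, and bPTH(7-34) also in substituted residues and dose. The loss of the first residues alone was therefore not tested. An immune-stimulating contaminant of the preparation, which came from another vendor than the bovine peptides, cannot be told apart from the peptide itself, because each peptide came as 1 preparation; interferon-stimulated genes, which such a contaminant could raise, had a median of +0.35, while Il6 was at -0.08. A biological effect of the hPTH(7-34) sequence stays open as an untested explanation. The rise was not particular to hPTH(7-34), since 9 of the 13 genes were also called higher with hPTH(1-34). The median of the 13 was +1.03 with hPTH(1-34), +0.83 with hPTH(1-31) and +0.69 with PTH(1-36). The genes were chosen against the same vehicle arrays, which biases these medians upward.

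The second pattern is the lower response score of PTH(1-36) than of hPTH(1-34), a difference of -0.0467. Without the sign by direction, the mean difference was -0.032 over genes higher with hPTH(1-31) and +0.062 over genes lower with it. In the deposited values both parts of the response were thus smaller, the decreases more so. Centring each array on its median adds 0.033 to the difference of every gene here, about the size of the first part. The smaller increases therefore depend on the processing, while the signed score difference was -0.0465 with centred arrays. Unequal distributions of the deposited values are argued against, since the difference was -0.0482 (95% interval -0.067 to -0.030) after quantile normalization. The quartiles were already near equal, so this step had little to change, and it cannot test the processing before deposit. The score difference does not rest on 1 array, since the value nearest 0 was -0.0395 (95% interval -0.060 to -0.019), without hPTH(1-34) replicate 2. A lower amount or activity of the PTH(1-36) preparation, which reached 92.4% of the hPTH(1-34) score, cannot be told apart from an effect of its structure, since 1 preparation at 1 dose was used, and the structural difference stays open as well.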

How the results depend on the processing

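The alternative that leaves out all arrays numbered 3 and the truncated-analog scores with genes chosen on other arrays were chosen after the data were seen, and all other alternatives were planned. With 3 arrays per group and no background value per gene, low signals limit what can be called, and counts over all transcript clusters or over fewer genes come from other numbers of tests. Quantile normalization left all 12 gene counts within 1.5 times. A change of at least 1.5-fold, a subset by construction, left 783, 805 and 701 genes for hPTH(1-34), hPTH(1-31) and PTH(1-36) against vehicle, and 825 and 908 for bPTH(3-34) and hPTH(7-34) against hPTH(1-34). Fitting only the 2 groups compared, with fewer degrees of freedom, gave 936 (902 shared), 928 (899 shared) and 606 (599 shared) against vehicle, 1217 (1146 shared) and 1425 (1337 shared) against hPTH(1-34), and 0 for hPTH(7-34) against vehicle, PTH(1-36) against hPTH(1-34) and hPTH(7-34) against bPTH(3-34). Without the arrays numbered 3, which leaves fewer samples, these counts were 1228 (1109 shared), 1140 (1037 shared), 960 (847 shared), 1213 (1114 shared), 1559 (1382 shared), and 0, 0 and 0.

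With eBayes trend and robust options, hPTH(7-34) gave 34 genes against vehicle (16 shared) and 18 against bPTH(3-34) (11 shared), bPTH(7-34) gave 1 against vehicle, and PTH(1-36) gave 3 against hPTH(1-34). That last contrast gave 2 with centred arrays, 3 without genes under the median level and 2 over all transcript clusters, where hPTH(7-34) against bPTH(3-34) gave 5. Of 138 list tests, 20 were called, 8 with an estimated correlation, 37 with fry directional and 65 with fry mixed, which tests another hypothesis. The score difference of hPTH(1-31) from hPTH(1-34) was 0.0306 over genes changed at least 1.5-fold, with an interval above 0 and an exact p = 0.2, and 0.0020 (95% interval -0.022 to 0.026; exact p = 0.667) without the arrays numbered 3. Over genes chosen without the vehicle or scored arrays the scores were -0.0077 for bPTH(3-34), 0.0010 for hPTH(7-34) and 0.0087 for bPTH(7-34). Beyond the alternatives whose construction is named, the cause was not tested.

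Leaving out 1 array at a time gave 1421 to 1677 genes for hPTH(1-34), 1481 to 1669 for hPTH(1-31), 1160 to 1499 for PTH(1-36) and 6 to 24 for hPTH(7-34) against vehicle. Against hPTH(1-34) it gave 0 to 3 for PTH(1-36), 1534 to 1707 for bPTH(3-34) and 1700 to 2133 for hPTH(7-34), and for hPTH(7-34) against bPTH(3-34) it gave 2 to 9. The score difference from hPTH(1-34) ran from 0.0088 to 0.0291 for hPTH(1-31) and from -0.0567 to -0.0395 for PTH(1-36). Of 224 values of named genes 178 were called, and 150 of these calls held in every fit without 1 array; with centred arrays 179 were called, with 1 lost and 2 gained, and no called value changed sign in any of these fits.

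With the replicate number as a block, the counts against vehicle were 2190, 2179, 1945, 0, 15 (13 shared) and 0 in the order of the report, and the score difference of hPTH(1-31) from hPTH(1-34) was 0.0203, with an interval of 0.00067 to 0.040 and an exact p = 0.3. Of the named-gene values 172 were called, with 7 calls lost (Wnt4 with hPTH(1-34), Tnf, Pstpip2 and Gm12250 with hPTH(7-34), and Nfkbie, Irf1 and Nlrp1c-ps for hPTH(7-34) against bPTH(3-34)) and 1 gained (Fos with PTH(1-36)). The labels give arrays of different groups only a number in common. Of 63 pairs of arrays with the same number 1 had a correlation over 0.1, with means of 0.0081, 0.030 and 0.051 for numbers 1, 2 and 3. Still, 14 of 21 arrays correlated best with arrays of their own number, more than a random match would give. Whether a number marks a common preparation or batch is not settled by these values, and the main model takes no account of it. On the second principal component (7.40% of the variance) the array numbered 3 was the highest of its group in all 7 groups, from 16.5 against -3.50 and 0.46 for PTH(1-36) to 2.16 against 1.87 and -5.27 for hPTH(7-34).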

Other observations

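The gene groups of this part were assembled after the values were seen, so their counts are not independent evidence, while the counts over other splits of the arrays were planned. Some enzymes that make hyaluronan and its sugar precursors rose with hPTH(1-34), and no group of this part was tested as a list. Beside the synthase Has2 (+1.89 ± 0.09, log2, SE), Gfpt2, which starts hexosamine synthesis (+2.29 ± 0.11), Ugdh, which makes UDP-glucuronate (+2.17 ± 0.08), and Uap1, which makes UDP-N-acetylglucosamine (+2.02 ± 0.08), were higher, and the hyaluronan-degrading Cemip (-1.77 ± 0.11) was lower. Of 13 such genes measured, 4 were called higher, 1 lower and 8 not called with hPTH(1-34), 6 and 1 with hPTH(1-31), and 5 and 1 with PTH(1-36). Genes of retinoid handling included the retinol dehydrogenase Rdh10 (+1.66 ± 0.13), the retinal dehydrogenase Aldh1a3 (+1.36 ± 0.20) and the retinoic acid carrier Crabp2 (+1.25 ± 0.12), with 5 of 18 higher and 3 lower with hPTH(1-34), 6 and 1 with hPTH(1-31), and 5 and 1 with PTH(1-36). When each array was centred on its median, hPTH(1-34) gave 4 of them higher and 3 lower.

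Some targets of the mechanosensitive regulators YAP and TEAD were lower. With hPTH(1-34), Ccn1 (-0.88 ± 0.10), Ccn2 (-1.07 ± 0.17) and the kinase Nuak1 (-1.17 ± 0.13) fell and the phosphatase Dusp1 (+0.73 ± 0.10) rose. In all 7 of 16 were lower and 1 higher with hPTH(1-34), 9 and 2 with hPTH(1-31), and 8 and 2 with PTH(1-36), and with centred arrays 8, 9 and 7 were lower. Sarcomere and actin-linked genes went both ways, with Nexn (-1.44 ± 0.10) and Sorbs2 (-1.19 ± 0.10) lower and Synpo2 (+1.98 ± 0.12) higher, 6 of 15 lower and 2 higher with hPTH(1-34), 6 and 2 with hPTH(1-31), and 5 and 2 with PTH(1-36), and with centred arrays 6, 5 and 4 were lower. Among heat-shock genes Hsph1 rose by 1.71 ± 0.09, with 4 of 17 higher and 1 lower with hPTH(1-34), 4 and 1 with hPTH(1-31), and 5 and 1 with PTH(1-36). Among cytosolic aminoacyl-tRNA synthetases Eprs rose by 1.43 ± 0.08, with 2 of 18 higher with hPTH(1-34) and 1 with each of the other intact analogs.

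Other splits of the same arrays were counted for each contrast and for the F test. With 100 splits of the 21 arrays into 7 groups of 3, only the real one gave as many as 2717 genes with the F test. The highest of the others gave 1. The share of 1 in 100 is under 0.05 and is the smallest that 100 splits allow. Other splits mix treatments within a group, which puts treatment differences into the spread and lowers their counts, here and in the contrasts below. A contrast of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split and the highest other gave 1917 and 0 genes for hPTH(1-34), 1930 and 0 for hPTH(1-31), 1603 and 1 for PTH(1-36), and 16 and 0 for hPTH(7-34) against vehicle. Against hPTH(1-34) they gave 2068 and 0 for bPTH(3-34), 2409 and 0 for hPTH(7-34), and 1 and 0 for PTH(1-36), and for hPTH(7-34) against bPTH(3-34) they gave 11 and 0, with 1 of the 10 splits as high as the real one in each of these 8 contrasts. For bPTH(3-34) and bPTH(7-34) against vehicle and for hPTH(1-31) against hPTH(1-34), limma gave 0 genes for the real split and 0 for the highest other, so all 10 were as high, with 1313, 1151 and 994 genes at an unadjusted p under 0.05 in the real split.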
